A study of Drosophila melanogaster with 16 samples.

How the data were processed

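The series compared ovaries of Drosophila melanogaster, kept at 25 degrees and aged 3 to 5 days, after tj-GAL4 or nos-GAL4 driven knockdown of piwi or of white. Per the labels' protocols, GRO-seq used nuclei of about 100 ovaries and ChIP-seq chromatin of 50 ovaries, with an antibody to H3K9me3 and an aliquot kept as input. The 16 samples were grouped by assay, driver and knockdown from their titles, with 1 sample in each group. Small RNAs and levels of host genes were not analysed here, so the lists of host genes written beforehand gave no value.

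Per the submitters' processing notes, Bowtie2 2.0.0 was used for all assays, TopHat2 2.0.5 for RNA-seq, DESeq 1.10.1 for RNA-seq and GRO-seq and SICER 1.1 for ChIP-seq, with genome build dm3. Which step each tool performed is not given in the sources used here. The deposited RNA-seq and GRO-seq tables give RPM (reads-per-million) per transposon, split into sense and antisense, per the file headers. The authors' ChIP-seq transposon table gives RPM in 4 input and 4 H3K9me3 libraries, and the ratio of H3K9me3 to input. A further pair of the authors' deposited tables gives, per element, the fold between the knockdowns, its log2 and p-values. Their 6 columns of scaled reads carry no sample name and were not used here. The deposited region lists give RPM per region in both libraries, a fold and an adjusted p-value, per the file headers.

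Every value of the ChIP-seq transposon table was, within 1e-06 reads, a whole number of reads for a library total of 2514000 to 3047000, which gave the reads behind each value. The RPM of the region lists were whole reads for all values within 1e-06 reads, with totals of 1435888 and 1451863 in tj piwi and tj white and 987157 and 1385901 in nos piwi and nos white. Of RNA-seq values under 1 RPM, those of both tj columns were sums of 2 best fitting step sizes within 1e-09 RPM, in 14 of 14 cases in piwi and 25 of 25 in white knockdown, but in nos piwi only 5 of 16 and in nos white 23 of 29 were, so the replicates behind a column could not be separated. Fractional reads were present in RNA-seq and GRO-seq and reads of related families could not be told apart.

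RNA-seq and GRO-seq changes were log2 ratios of RPM + 1 in piwi over white knockdown, for elements with a mean of at least 1 RPM over the 4 columns of a strand. The tests planned for RNA-seq needed 2 columns per group and were replaced, as laid down beforehand, by values side by side, so no model was fitted and no adjusted p-value was computed. A size of 2-fold was chosen after seeing the data as the mark for counting. H3K9me3 was the ratio of H3K9me3 over input in piwi to the same in white knockdown, for elements with at least 100 reads in each of the 4 libraries, with a 95% interval from the sum of the reciprocal read numbers. Regions carry the authors' fold, which holds a small offset, and an exact Clopper-Pearson 95% interval from the recovered reads. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only.

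Element lists were fixed before the data were examined: a soma list of 16, a germline list of 18 and a telomere list of 5, the last contained in the germline list, and class lists of 58 LTR, 36 LINE-like and 21 DNA elements. The 10 elements in no class list stayed out of these. Each list's median was ranked among 10000 random lists of equal size drawn from 5 level bins, as a description of these libraries. Named elements were the 8 largest ratios each way in each assay and the members of the lists. That rule was set for GRO-seq and H3K9me3 and was used for RNA-seq too, since the RNA-seq rule needed a test. Further elements named beside them were chosen after their values were seen. Named regions were the 5 largest folds each way with at least 100 reads in the higher library. Coordinates are 1-based.

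Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Overlap counts were checked against bedtools 2.31.1 and were equal. On simulated reads with 20 elements changed 2-fold, 100% of the changes under tj and 99.7% under nos were found, and 94.8% and 95.4% of the intervals held the true value. With 200 of 5144 tj and of 5421 nos regions changed 2-fold, 82.5% and 80.0% were found. Of unchanged elements 5.06% and 4.65% were called, and of unchanged regions 3.92% and 4.00%. The simulated reads held counting error alone, with known library totals. They check the calculation and not differences between libraries, doubtful totals or changes under 2-fold. Alternatives were other pseudocounts (0.1 and 5), no level filter or a mean of 10 RPM, centring on the median, H3K9me3 without input, other read minimums, stricter region thresholds and other overlaps.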

Results

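Ovaries of Drosophila melanogaster aged 3 to 5 days were compared after knockdown of piwi, a nuclear Argonaute protein that is guided by small RNAs to transposon transcripts, and after knockdown of white, an eye colour gene that served as the control. The knockdown was driven either by tj-GAL4, a driver active in the somatic cells of the ovary that surround the germline, or by nos-GAL4, a driver active in the germline. Steady-state RNA was measured by RNA-seq, nascent RNA by GRO-seq (sequencing of transcripts extended in a nuclear run-on reaction), and the histone mark H3K9me3, a mark of silent chromatin, by ChIP-seq with a matched input library. Each of the 4 combinations of driver and knockdown had 1 GRO-seq sample, 1 RNA-seq sample, 1 H3K9me3 sample and 1 input sample, 16 in all. The series states 2 replicates for RNA-seq, but the deposited table holds 1 column per condition and strand, so each RNA-seq value is the authors' value with no spread. No comparison had replicate values, and no difference described here has a replicate check.

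The tables listed transposon families by name, 119 in RNA-seq and 122 in GRO-seq. Levels of piwi and white themselves were not analysed here, so the knockdowns were not checked. The ChIP-seq libraries of the transposon table held 2514000 to 3047000 reads, as recovered from the steps between their values. Transposons took 8.02% to 9.47% of the input reads and 28.4% to 30.6% of the H3K9me3 reads. The GRO-seq values moved in steps that correspond to about 34568000 reads, by the best fitting step, in tj piwi knockdown, 32549800 in tj white, 27040000 in nos piwi and 27097800 in nos white, but only 59.8% to 73.0% of values under 100 RPM were whole multiples within 0.0051 RPM, against 27.6% to 35.3% by chance at 1 given step. The RNA-seq values under 1 RPM fitted 2 step sizes per column in both tj columns, which correspond to libraries of 6500834 and 4046560 reads in tj piwi and 7913694 and 2708244 in tj white knockdown if each column is the mean of 2 libraries and each step 1 read. The depth of the nos RNA-seq libraries was not recovered, since 5 of 16 such values fitted in piwi and 23 of 29 in white knockdown.

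The first question was which transposon RNAs accumulate when piwi is knocked down under the tj driver. Of 113 elements with a mean of at least 1 RPM (reads-per-million), 44 had at least 2-fold more sense RNA in piwi than in white knockdown and 2 had at least 2-fold less. The largest ratios belonged to LTR retrotransposons. Sense RNA of ZAM was 5192 RPM against 94.5 RPM in the control (54.4-fold), and gypsy6 was 420 against 4.56 RPM (75.6-fold). HMS-Beagle2 was 71.9-fold higher, Tirant 62.8-fold, gypsy5 44.3-fold, springer 33.4-fold and gypsy 18.3-fold.

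Of the 16 elements of the soma list, families known from ovarian somatic cells, 15 were at least 2-fold higher under tj, with a median log2 ratio of 2.66. That median lay at the 99.99th percentile of 10000 random lists of equal size matched on level. Within the list, blood was 11.3-fold higher and Idefix 4.48-fold higher, while mdg1 was 2.08-fold higher. The germline list had 6 of 18 members at least 2-fold higher and a median log2 ratio of 0.70, at the 15.7th percentile. The median of all elements was 0.69. The matching level included the piwi knockdowns, so the percentile does not place the list below other elements. The telomere list, the retrotransposons HeT-A, TAHRE and TART that maintain chromosome ends, had 1 of 5 members at least 2-fold higher, TART-B at 2.06-fold. Input reads of TART-B were 2.33 times the control under tj, so its RNA ratio did not exceed its input ratio. By class, 33 of 56 LTR elements, 8 of 33 LINE-like elements and 0 of 18 listed DNA transposons were at least 2-fold higher. Hobo, which is in no class list and so is not among these 18, was 4.09-fold higher, with input reads 1.69 times the control. The class medians were 1.17, 0.43 and 0.09 on the log2 scale, and after centring on the median element the LINE-like median was -0.25, the DNA median -0.60 and the telomere list -0.28. The 2 elements with at least 2-fold less sense RNA were copia, at 6027 against 17433 RPM, and invader1, at 11.8 against 31.9 RPM. Ratios are on the RPM + 1 scale, which understates the change of low elements. The median element was 1.61-fold higher (log2 0.69), and after centring on that median 24 elements were at least 2-fold higher and 15 lower.

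Under the nos driver, the question was the same for the germline. Sense RNA was at least 2-fold higher in piwi knockdown for 59 of the 113 elements and at least 2-fold lower for 0. The 5 telomeric elements were all far higher. HeT-A was 8533 RPM against 24.3 RPM (337-fold), TART-B 2145 against 7.69 RPM (247-fold), TART-C 919 against 4.07 RPM (181-fold), TAHRE 3409 against 26.5 RPM (124-fold) and TART-A 1128 against 10.4 RPM (98.8-fold). Among LTR elements, 3S18 was 152-fold higher, mdg3 138-fold, Burdock 113-fold and GATE 102-fold.

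The germline list, which contains the telomeric elements, had 12 of 18 members at least 2-fold higher and a median log2 ratio of 4.61, at the 99.1st percentile of matched random lists. That median leans on the telomeric elements. Without them the middle member would be jockey, at a log2 ratio of 1.51, which is also the median of the soma list. Max-element was 12.5-fold higher and I-element 5.41-fold, whereas roo was 1.22-fold, Doc 1.19-fold and Rt1a 0.974-fold the control. The soma list had 9 of 16 members at least 2-fold higher and a median log2 ratio of 1.51, at the 27.1st percentile. In that list blood was 15.7-fold higher, whereas ZAM was 1.28-fold, gypsy5 1.02-fold and gypsy 0.766-fold the control. By class, 35 of 56 LTR elements, 17 of 33 LINE-like elements and 4 of 18 listed DNA transposons were at least 2-fold higher. The class medians were 1.95, 1.22 and 0.20 on the log2 scale, and after centring the DNA median was -0.90. The median element was 2.14-fold higher. After centring on that median 38 elements were at least 2-fold higher and 15 lower.

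**Figure D1:**
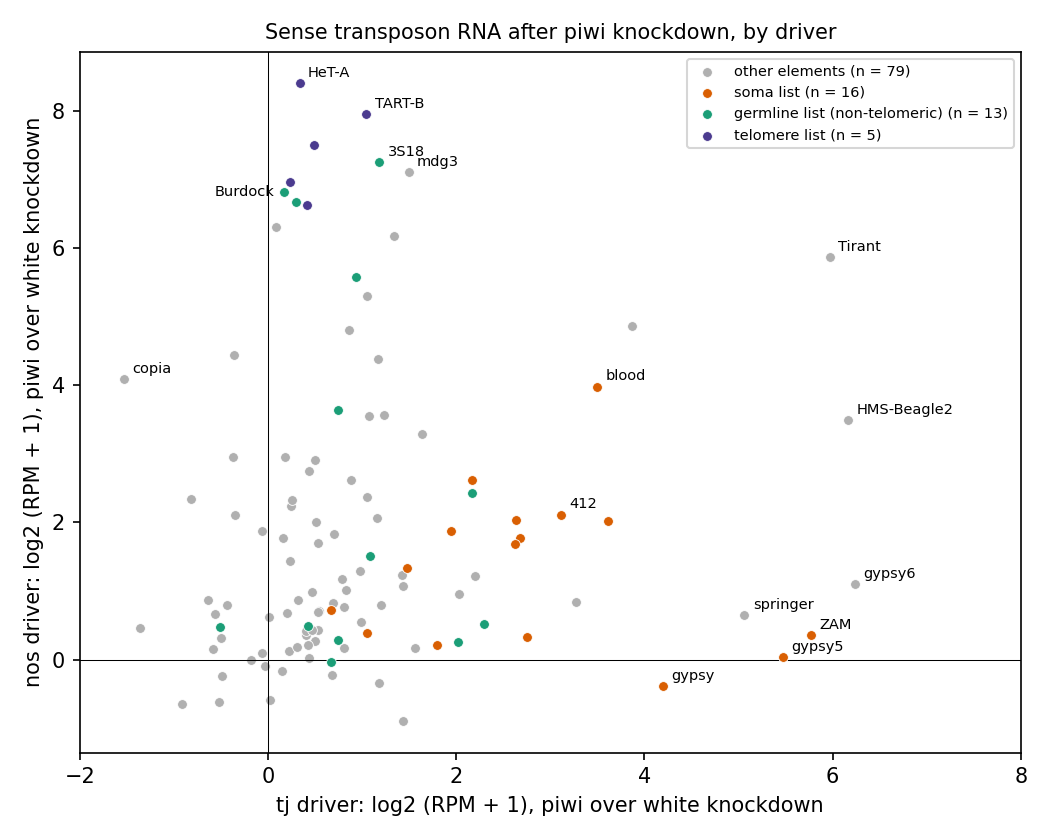
Each point is 1 of 113 transposons, with the log2 ratio of sense RNA (RPM + 1) in piwi over white knockdown under the tj driver on the horizontal axis and under the nos driver on the vertical axis, coloured by the soma, germline and telomere lists. HeT-A lies at 0.34 and 8.40, ZAM at 5.77 and 0.36, and Tirant at 5.97 and 5.87.

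Antisense RNA was measured in the same libraries for 109 elements. Under tj, 19 elements had at least 2-fold more antisense RNA in piwi knockdown, with Tirant 14.0-fold, springer 13.0-fold, gypsy5 11.6-fold and gypsy 7.59-fold higher, and 1 element, copia, had at least 2-fold less. Under nos, 53 elements were at least 2-fold higher and 0 lower, with HeT-A 205-fold, 3S18 149-fold, TAHRE 87.1-fold and TART-A 67.3-fold higher. The median log2 ratio of the germline list was 2.49 under nos and 0.33 under tj, and that of the soma list was 0.28 under nos and 0.44 under tj. With a pseudocount of 5 the counts of higher elements were 11 under tj and 29 under nos. After centring 11 were higher and 1 lower under tj, and 24 were higher and 11 lower under nos.

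The responses under the 2 drivers were set side by side, without a test of the difference. Sense RNA of 29 elements was at least 2-fold higher under both drivers, where independent lists of these sizes would share 23.0. Another 15 passed that size under tj alone and 30 under nos alone. Across the 113 elements, which are not independent replicates, the log2 ratios had a Pearson r of 0.05 and a Spearman rho of 0.15. The largest excesses under tj were those of gypsy5 (log2 ratio 5.47 under tj and 0.03 under nos), ZAM, gypsy6, gypsy and springer. The largest excesses under nos were those of HeT-A, TART-C, TART-B, TAHRE and Burdock, the last with log2 ratios of 0.17 under tj and 6.81 under nos. With a pseudocount of 5 the number higher under both drivers was 15, and after centring it was 7.

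GRO-seq asked whether transcription itself differed. Under tj, 26 of 122 elements had at least 2-fold more nascent sense RNA in piwi knockdown and 0 had at least 2-fold less. ZAM was 888 RPM against 5.82 RPM (130-fold), gypsy5 was 30.3-fold higher, Tirant 20.6-fold, mdg1 17.7-fold and HMS-Beagle2 11.3-fold. The soma list had 12 of 16 members at least 2-fold higher and a median log2 ratio of 1.71, above the medians of all 10000 matched random lists. The germline list had 1 of 18 members at least 2-fold higher and a median of 0.42, and HeT-A (36.7 RPM against 43.8 RPM) and TAHRE (0.777-fold) were lower than the control. The member that was higher was TART-B, at 2.62-fold, beside input reads 2.33 times the control. By class the median log2 ratios were 0.66 for LTR, 0.18 for LINE-like and 0.27 for DNA elements. After centring, the LINE-like and DNA medians were -0.20 and -0.12, and 16 elements were at least 2-fold higher and 0 lower. Antisense nascent RNA was at least 2-fold higher for 17 elements and lower for 0, ZAM the highest at 17.2-fold, and after centring for 10 and 2.

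Under nos, 42 of 122 elements had at least 2-fold more nascent sense RNA and 1, frogger, had at least 2-fold less (7.40 against 25.8 RPM). Transpac was 1006 against 62.6 RPM (15.8-fold), Tirant was 14.0-fold higher, 3S18 12.0-fold, gypsy12 8.81-fold and micropia 6.78-fold. The 5 telomeric elements were all at least 2-fold higher, HeT-A at 5.14-fold, TART-B at 4.77-fold and TART-C at 2.09-fold, and their median log2 ratio of 2.11 lay at the 96.7th percentile. The germline list had 11 of 18 members at least 2-fold higher, with a median log2 ratio of 1.39 at the 96.6th percentile. Without the telomeric elements its middle member would be jockey, at 0.95. The soma list had 5 of 16, with a median of 0.61 at the 27.4th percentile, though above the 0.52 of all elements. By class the median log2 ratios were 1.04 for LTR, 0.37 for LINE-like and 0.19 for DNA elements. After centring, 27 elements were at least 2-fold higher and 8 lower, and the LINE-like and DNA medians were -0.15 and -0.33. Antisense nascent RNA was at least 2-fold higher for 18 elements and lower for 0, gypsy11 the highest at 5.29-fold, and after centring for 17 and 3.

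Nascent and steady-state changes were then set side by side, element by element. Under tj, 24 elements had at least 2-fold more sense RNA in both assays, and the RNA-seq ratio was the larger for 18 of them. For mdg1 the nascent ratio was larger, with log2 ratios of 4.14 in GRO-seq and 1.05 in RNA-seq, and for F-element the steady-state ratio was larger, at -0.31 and 2.30. Under nos, 39 elements passed that size in both assays, and the RNA-seq ratio was the larger for 38 of them, by a median log2 difference of 1.94. The gap was widest for 4 of the 5 telomeric elements, TART-C, HeT-A, TART-B and TAHRE. TART-C had log2 ratios of 1.06 in GRO-seq and 7.50 in RNA-seq, and HeT-A had 2.36 and 8.40. In each driver 20 elements passed the size in RNA-seq alone and 2 in GRO-seq alone. Across 113 elements, which are not independent replicates, Pearson r was 0.77 and Spearman rho 0.58 under tj, and 0.80 and 0.79 under nos. The assays were scaled separately and background that does not respond lowers either ratio by an unknown amount. A gap between the ratios therefore cannot be assigned to steps after transcription.

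**Figure D2:**
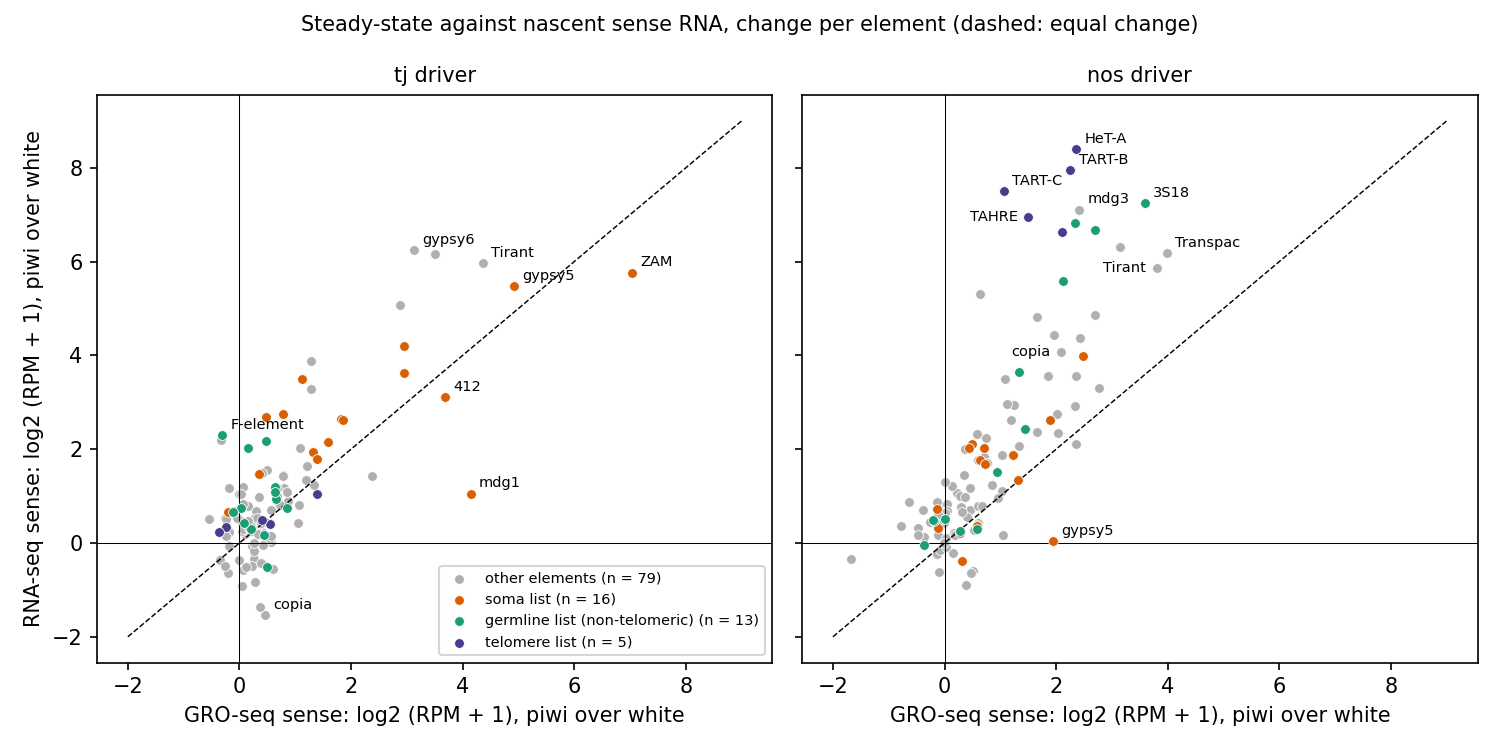
Each point is 1 of 113 transposons, with the log2 ratio of nascent sense RNA in piwi over white knockdown on the horizontal axis and that of steady-state sense RNA on the vertical axis, 1 panel per driver, and the dashed line marks equal change. Telomeric elements under nos stand far above the line (TART-C at 1.06 and 7.50), and mdg1 under tj stands below it (4.14 and 1.05).

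H3K9me3 over transposons was taken relative to input, to ask whether the mark was lost along with silencing. Under tj, 0 of 114 elements were 2-fold higher or lower in piwi knockdown. The chromatin came from ovaries, with germline and somatic cells together. The mark in cells where a driver is not active therefore lowers any change by an unknown amount. The median ratio was 0.909, and the 95% counting interval lay below 1 for 54 elements and above 1 for 5. The soma list had a median log2 ratio of -0.23, at the 0.665th percentile of matched random lists, with 13 of 16 intervals below 1. Within it ZAM had 0.634 times the control enrichment (95% counting interval 0.571 to 0.704), gypsy5 0.637 (0.534 to 0.761) and blood 0.842 (0.796 to 0.891), while gypsy was at 0.995 (0.924 to 1.07). Input reads of ZAM and gypsy5 were themselves 1.59 and 1.87 times the control, and without input their log2 ratios of H3K9me3 were 0.01 and 0.25 and the median of the soma list was -0.05. The germline list had a median log2 ratio of -0.12 and HeT-A was at 1.08 (1.01 to 1.15). TAHRE had a log2 ratio of -0.007. Input reads of HeT-A and TAHRE were 0.617 and 0.506 times the control, so without input both lay below the control. The median log2 ratio was -0.17 for LTR, -0.10 for LINE-like and -0.14 for DNA elements. Bari1, a DNA transposon, had the lowest ratio, 1.74-fold below the control. After centring on the median, 20 intervals lay below 1 and 22 above, and the germline and LINE-like medians were 0.02 and 0.04 and that of the soma list -0.10. The direction under tj also rests on the library totals, because 2 of the authors' deposited tables imply different ones, and with the other set 10 intervals lay below 1 and 46 above, and the soma list had a median log2 ratio of 0.02 with 4 of 16 intervals below 1 and 4 above.

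Under nos, 6 of 115 elements were at least 2-fold lower in H3K9me3 over input and 0 were 2-fold higher. TART-B was at 0.122 times the control (95% counting interval 0.105 to 0.142), HeT-A was at 0.162 (0.146 to 0.181), TAHRE at 0.305 (0.277 to 0.336) and TART-A at 0.336 (0.270 to 0.419). TART-C was at 0.116 (0.0899 to 0.149) but had 99 H3K9me3 reads in piwi knockdown, under the minimum of 100. The remaining 2 were Bari1, 3.00-fold lower, and 3S18, 2.09-fold lower. The 4 telomeric elements past the minimum had a median log2 ratio of -2.17, and the 17 germline elements a median of -0.43 with 15 intervals below 1, lower than the medians of all 10000 matched random lists. Jockey was at 0.525 (0.493 to 0.559) and Burdock at 0.549 (0.501 to 0.601), whereas GATE, with 102-fold more RNA, was at 1.01 (0.961 to 1.07). The soma list had a median of -0.15, at the 56.9th percentile, with 10 of 16 intervals below 1 and 1 above. The median was 0.02 after centring, 0.0088 without input and -0.41 with the other set of library totals, where 15 intervals lay below 1 and 0 above. Without input the median of the telomere list was -2.27 and that of the germline list -0.28. The median log2 ratio was -0.22 for LTR, -0.20 for LINE-like and 0.05 for DNA elements. Intervals lay below 1 for 70 elements and above 1 for 7, after centring for 28 and 26, and with the other set of totals for 97 and 2.

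**Figure D3:**
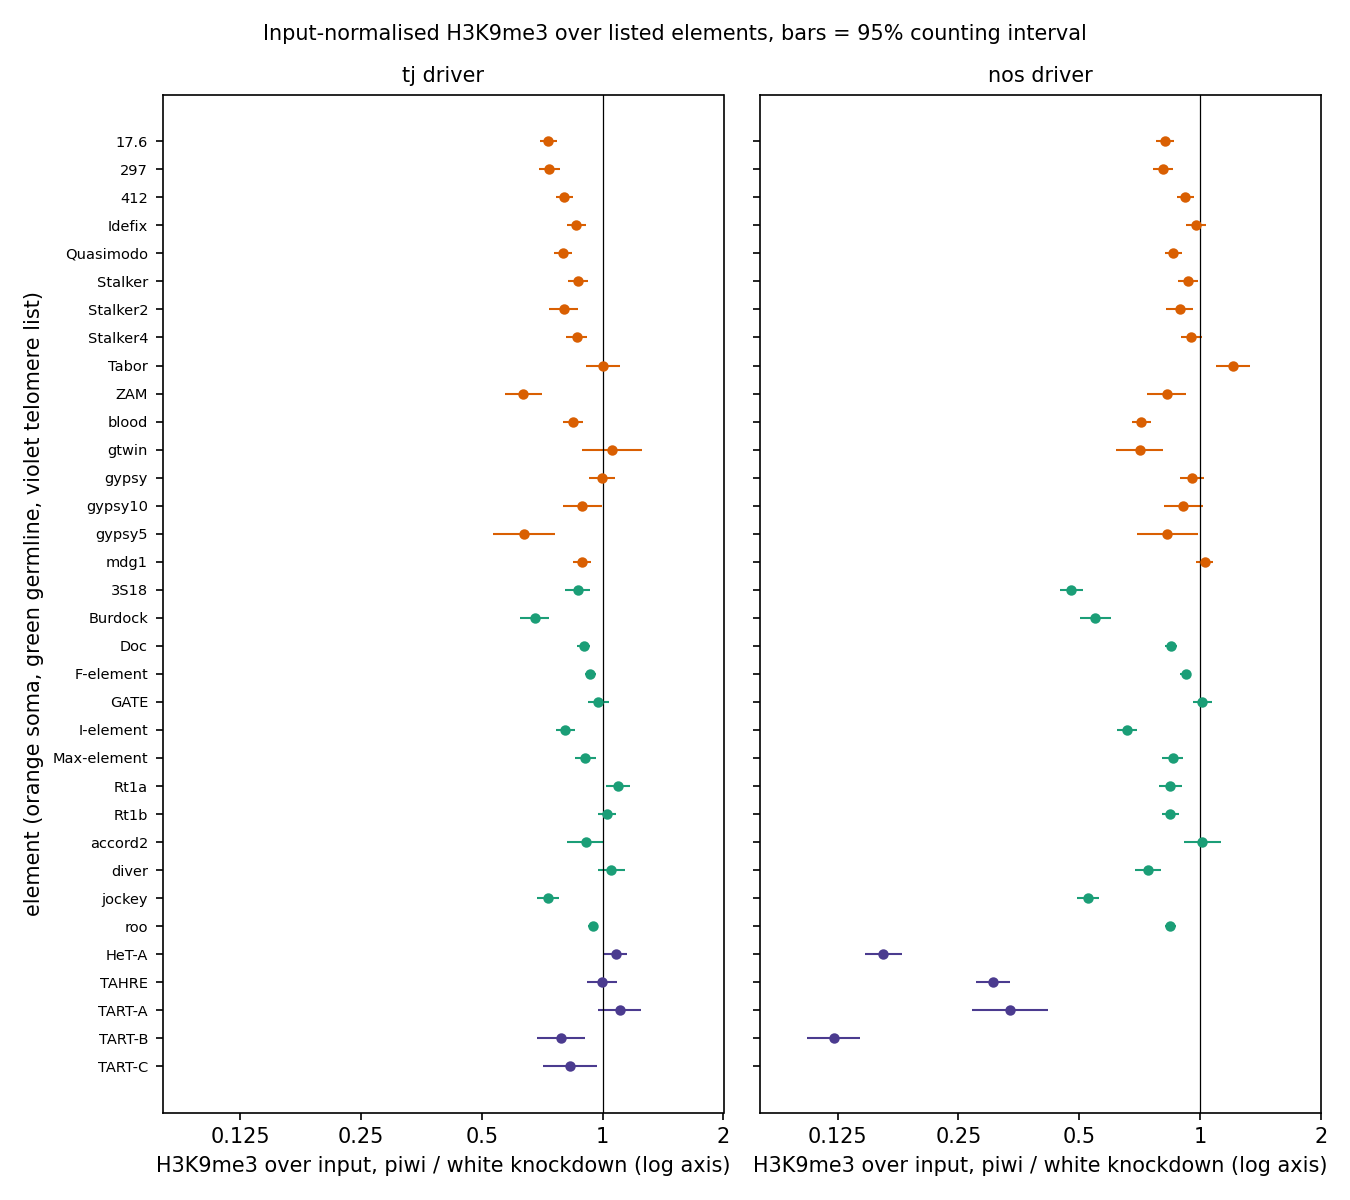
Points give the ratio of H3K9me3 over input in piwi to white knockdown (log axis) for elements of the soma, germline and telomere lists with at least 100 reads in each library, 1 panel per driver, and bars are 95% counting intervals from the reads of single libraries. Under nos TART-B and HeT-A stand at 0.122 and 0.162, and under tj at 0.788 and 1.08.

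Across elements, larger nascent increases went with lower H3K9me3 over input, but under tj the relation turned without input. Under tj the Pearson r between the log2 ratios was -0.44 and the Spearman rho -0.38 over 114 elements, and under nos they were -0.42 and -0.38 over 115 elements. Elements are not independent replicates, and 4 such correlations were computed. With the H3K9me3 libraries alone, without input, Pearson r was 0.20 under tj and -0.24 under nos. Of the 24 elements with at least 2-fold more nascent RNA under tj, 22 (91.7%) had an H3K9me3 ratio below 1, as did 93 of all 114 elements (81.6%). Under nos 36 of 39 (92.3%) did, beside 90 of 115 (78.3%). With the other set of library totals the tj numbers were 10 of 24 and 25 of 114, and without input 7 of 24 and 64 of 114. Under nos they were 39 of 39 (100%) and 109 of 115 (94.8%) with the other totals, and 21 of 39 (53.8%) and 66 of 115 (57.4%) without input.

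Along the genome, the authors' region lists (build dm3) set H3K9me3 in piwi knockdown against white knockdown. The lists give RPM of the H3K9me3 libraries alone, so their folds are not corrected for input. Under tj the lists held 5144 regions with a median fold, as given by the authors, of 0.983. In 399 regions the mark was at least 2-fold higher and in 447 at least 2-fold lower. Under nos they held 5421 regions with a median fold of 1.12, 599 at least 2-fold higher and 701 lower. On the arms 2L, 2R, 3L, 3R and X, 376 regions were higher and 632 lower under nos, and on chromosome 4 and the heterochromatin and unplaced scaffolds 223 were higher and 69 lower, with a median fold of 1.26. Chromosome 4 alone went the other way, with 2 of 115 regions higher and 21 lower and a median fold of 0.834. The excess of gains thus lay on the scaffolds. Under tj the arms held 321 higher and 379 lower regions. The authors' FDR lay under 0.05 for 1175 regions under tj and 2020 under nos. It was below 1 for 0 regions with a fold under 1, so it reads as a test of gain alone, and it compares 2 libraries, not the conditions.

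Named regions were those with the largest fold and at least 100 reads in the higher library. Under tj the largest gain was at 2L 8024001 to 8032000, with 739 reads in piwi and 31 in white knockdown (23.4-fold, exact 95% counting interval 16.8 to 35.7), and the next lay at 2L 7999001 to 8014000, 22.2-fold. The largest losses were at 3R 14831001 to 14837500, with 11 against 235 reads (19.5-fold lower, 11.6 to 42.9), and at 3R 1498001 to 1505000, with 27 against 469 reads (16.6-fold lower). Under nos the largest gain was at X 14337001 to 14340000, with 115 against 4 reads (32.6-fold, 15.3 to 151), and 2L 8003001 to 8013000 was 10.8-fold higher. Under nos 3L 22501 to 27000 had 0 reads in piwi knockdown against 127 in white, where the exact interval excludes less than a 24.2-fold loss, and 3R 1368501 to 1373500 had 2 against 216 (51.5-fold lower, 21.0 to 639). Genes at these positions were not analysed here. With at least 100 reads required in the higher library, 66 regions were higher and 118 lower under tj, and 74 and 178 under nos. With the library totals of the table of transposons, 392 regions were at least 2-fold higher and 881 lower under nos and the median fold was 0.951, and on chromosome 4 and the scaffolds together 111 were higher and 111 lower with a median fold of 1.07. Chromosome 4 was not counted apart with these totals, which lower every nos fold. With the lists' own totals it had 2 regions higher and 21 lower.

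The region lists of the 2 drivers were compared by overlap of at least 1 bp. Of all 5144 tj regions, 82.6% overlapped some nos region, and 2134 of the 5421 nos regions had a fold below 1. Of the 2692 tj regions with a fold below 1, 1119 (41.6%) overlapped a nos region with a fold below 1, with 3587.5 kb in common. Of the 2452 with a fold above 1, 1511 (61.6%) overlapped a nos region with a fold above 1, with 4279.5 kb in common. Of the 447 tj regions at least 2-fold lower, 182 (40.7%) overlapped such a nos region, against 8.26% of all tj regions, and of the 399 at least 2-fold higher, 118 (29.6%) did, against 6.82%. The region at 3R 14831001 was 19.5-fold lower under tj and 10.3-fold lower under nos, and the one at 2L 8024001 was 23.4-fold and 8.59-fold higher.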

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

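The tests of library totals and of regions shared between drivers were chosen only after the results were seen.

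Copia RNA moved in opposite directions under the 2 drivers, a difference that was not tested. Its sense RNA had a log2 ratio of -1.53 under tj and 4.08 under nos, a difference of -5.61, and its antisense RNA differed by -5.58. The control levels were far apart, 17433 RPM of sense RNA in tj white and 301 RPM in nos white knockdown, while the piwi knockdowns stood at 6027 and 5120 RPM. Nascent copia RNA was higher in piwi knockdown under both drivers, 1.37-fold under tj and 4.27-fold under nos.

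Input libraries, used only as a denominator, held more reads of many elements in piwi knockdown. The counting interval of the input ratio lay above 1 for 49 of 114 elements and below 1 for 12 under tj, and above 1 for 68 of 116 and below 1 for 8 under nos. TART-B had 901 reads against 359 under tj and 1094 against 567 under nos, whereas HeT-A had 1955 against 2948 and 1954 against 2997. Under tj ZAM had 1263 against 739 and gypsy5 535 against 266, while their H3K9me3 reads were 2743 against 2714 and 868 against 726.

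The authors' deposited tables of H3K9me3 comparisons gave a fold above 1 for 106 of 114 elements under tj and below 1 for 101 of 115 under nos. The folds of the authors' deposited table imply a piwi over white ratio of library totals of 0.842 under tj, which is the ratio of the nos libraries, and under nos that of the tj libraries, with deviations of at most 0.0328%. With the totals of the transposon table the gap between the drivers' median log2 ratios was -0.0056, against 0.50 in the authors' deposited table, so for the median element a difference of the mark cannot be told apart from an exchange of totals in 1 of the tables, which may account for the gap. Over input, HeT-A differed between the drivers by a log2 of 2.73 and TART-B by 2.69 with the totals of the transposon table, more than the gap that an exchange brings. The region lists, with ratios of 0.989 under tj and 0.712 under nos, run in the direction of the transposon table, but they use other read sets and leave open which table holds the exchange.

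Regions with at least 2-fold different H3K9me3 were shared between the drivers in both directions. The same direction was seen in 300 overlaps and the opposite direction in 22, a ratio of 13.6, which argues against chance or low read numbers. Of the overlaps in the same direction 89.7% lay on the arms, as did 82.7% of the 846 tj regions changed at least 2-fold, and 118 were gains. A difference in background between the white and piwi knockdown lines, such as insertions carried by 1 line, may produce both gains and losses at fixed sites. For gains, loss of Piwi and line background cannot be told apart here, since each knockdown had its own line and 1 library. If Piwi loss acted only in a driver's own cells, the parts lost under tj and nos could not together exceed the whole mark. The 182 shared losses, at least 2-fold under both drivers, reach or pass that bound. The largest had folds of 0.051 to 0.075 under tj and 0.052 to 0.153 under nos. For losses this argues against such confined loss of Piwi as the only cause, though the folds are not corrected for input.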

How the results depend on the processing

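The 4-fold size, the summed strands, the authors' deposited folds, both sets of other library totals, all scalings of the soma list intervals and of elements with more nascent RNA, the list medians and correlations of H3K9me3 without input and the 100-read minimum for regions were chosen only after the data were seen. No paired analysis was possible because the RNA-seq table holds 1 column per condition and strand with no replicate number. The fits without trend, with only the 2 groups compared or with each replicate left out, and the set tests, were not run for the same reason. Of the comparisons of main results with alternatives 236 stayed within 1.5 times, or 0.1 for correlations, 85 moved further and 12 reversed, and for named elements, with H3K9me3 held to its counting interval, these were 265, 76 and 6. An H3K9me3 median counts as reversed from a log2 of 0.1. Unless the construction of the alternative shows it, the cause was not tested. Depth limits low elements: ratios of elements near 1 RPM rest on the pseudocount, and intervals cover counting error in 1 library.

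Centring on the median element subtracts the same log2 value from every element. Sense RNA was then at least 2-fold higher for 24 and lower for 15 elements under tj, and for 38 and 15 under nos, with 7 higher under both drivers. Antisense RNA was higher for 11 elements under tj, and for 24 with 11 lower under nos. Nascent sense RNA was higher for 16 elements under tj, and for 27 with 8 lower under nos. Nascent antisense RNA was higher for 10 and lower for 2 elements under tj, and lower for 3 under nos. The RNA-seq medians under tj and nos became 1.97 and 0.42 for the soma list, 0.016 and 3.51 for the germline list, -0.28 and 6.41 for the telomere list, 0.49 and 0.85 for LTR, -0.25 and 0.12 for LINE-like and -0.60 and -0.90 for DNA elements. H3K9me3 ratios lay below 1 for 57 elements under each driver, with intervals below and above 1 for 20 and 22 under tj and 28 and 26 under nos. Of the soma list 8 intervals lay below 1 under tj and 4 under nos. The H3K9me3 medians reversed to 0.017 for the soma list under nos, and under tj to 0.016 for the germline list and 0.0025 for DNA elements.

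With a pseudocount of 0.1, sense RNA was at least 2-fold lower for 4 elements under tj and 2 under nos, and nascent sense RNA for 2 under nos. With a pseudocount of 5, antisense RNA was higher for 11 elements under tj and 29 under nos, sense RNA for 15 under both drivers, and the telomere median under nos was 6.76. With a mean of at least 10 RPM, which leaves fewer elements, antisense RNA was higher for 12 under tj and 30 under nos, sense RNA for 18 under nos alone, and the median sense ratio under nos was 2.03. At 4-fold, 22 elements had more sense RNA under tj, and nascent RNA was higher for 11 under tj and 21 under nos.

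Without input, H3K9me3 intervals lay above 1 for 22 elements under tj and 35 under nos, and below 1 for 44 under nos. Of the soma list 8 lay below 1 under tj and 6 under nos, where its median reversed to 0.0088. Of elements with at least 2-fold more nascent RNA, 7 lay below 1 under tj and 21 under nos, as did 64 and 66 of all elements. The Pearson r between nascent and H3K9me3 change reversed to 0.20 under tj and was -0.24 under nos. The log2 ratio reversed under tj for ZAM (0.011), gypsy5 (0.25), HMS-Beagle2 (0.081), hobo (0.25) and G2 (-0.057), and under nos for hopper (-0.0022), each with a counting interval that excluded 1 with input. Beyond the 6 counted, HeT-A under tj turned too. Its log2 ratio was 0.106 over input, but its input was 0.617 times the control, so without input it lay below the control. With the other driver's H3K9me3 totals, intervals lay below 1 for 10 and above 1 for 46 under tj, and above 1 for 2 under nos. Under tj the median of all elements then reversed to 0.12, and those of the soma list to 0.020, the germline list to 0.13, LTR to 0.082 and DNA elements to 0.12, with 4 soma intervals below 1 and 10 elements with more nascent RNA below 1. By the fold in the authors' deposited table, 8 elements lay below 1 under tj and the median reversed to 0.23. With at least 1000 reads, ratios lay below 1 for 48 elements under tj and 50 under nos, intervals above 1 for 3 under tj, and under nos intervals below and above 1 for 44 and 2, with 1 element at least 2-fold lower.

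Stricter region lists hold fewer regions by construction. With an FDR under 1e-10, 222 regions under tj and 325 under nos had a fold above 1. With a fold of at least 2 these were 399 above and 447 below under tj, and 599 and 701 under nos. On the arms 1390 were above 1 and 1646 below under tj, and under nos 1630 were above 1 and 376 at least 2-fold higher. With at least 100 reads in the higher library 66 were higher and 118 lower under tj, and 74 and 178 under nos. With the library totals of the table of transposons, 392 were at least 2-fold higher under nos, on chromosome 4 and the scaffolds together 111 were higher and 111 lower, and the median log2 fold under nos reversed to -0.073.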

Other observations

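The tests of antisense RNA were chosen only after the result was seen.

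Some elements had much antisense RNA in every condition, including the controls. In 12 elements it exceeded 200 RPM in all 4 RNA-seq columns, led by mdg1 (26618 RPM in tj white knockdown), BS (12739), ZAM (6337), opus (5875) and Tabor (5054). They held 95.3% of antisense RPM in tj white and 98.1% in nos white knockdown. Their median log2 ratio of piwi over white was -0.42 under tj and 0.09 under nos.

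Steady-state antisense RNA exceeded nascent antisense RNA in 11 of the 12 on the mean of the 4 columns, and in Doc it was lower, at 331 against 528 RPM. The set was chosen on its steady-state level, which by itself favours such an excess, so no conclusion is drawn from that count. If transcription rate alone set the level, the ratio of steady-state to nascent antisense RNA would be about equal across the set. The SD of its log2 over the 12 elements was 2.27 to 2.77 in the 4 pairs of columns, and that of 1 element over the 4 pairs had a median of 0.55 and was highest, at 2.21, for ZAM, which argues against rate alone, as measured by GRO-seq. Reads from only 1 shared RNA covered alike in both libraries would give equal changes. Under tj the log2 ratios ran from -0.60 for Rt1a to 0.29 for HMS-Beagle2 with an SD of 0.272. Counting error at the fitted depth divided by 10 would give 0.0702 (chi-square per degree of freedom 18.9). This argues against such an RNA as the only source for the whole set. Under nos the SD was 0.167, with no depth recovered to set it against. An RNA shared by part of the set, covered unevenly between libraries, or mixed with an element's own antisense reads stays open. No biological explanation was tested.

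P-element had 103 RPM of nascent sense RNA in tj white and 385 RPM in nos white knockdown but 14 and 37 input reads. NOF had 75 input reads in tj white and 426 in nos white knockdown, and 3.35 and 72.2 RPM of nascent sense RNA. The input ratios of the 2 drivers had a Pearson r of 0.67 over 114 elements, which are not independent replicates.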
